A study of Drosophila melanogaster with 6 samples.

How the data were processed

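Total RNA from eye-antennal discs of 6 samples, 3 of ey-Gal4 with UAS-dTet and 3 of ey-Gal4 with w1118, was made into stranded total RNA libraries, per the labels' protocols, which call the 3 samples of each group biological replicates. Reads were aligned with HISAT2 2.2.0 to the dm6 genome after FastQC 0.12.1, per the submitters' processing notes. Per the file headers, the deposited counts are whole read pairs per gene symbol, made by the authors with featureCounts 2.0.6 on the FlyBase 6.45 annotation, over exons, with both mates mapped and the strand setting 2 for reverse-stranded libraries. By that program's defaults, pairs that map to several places or overlap several genes are left out, so near-identical copies (histones, small RNAs, paralogs) can be undercounted. Depletion of ribosomal RNA is not given in the sources used here. The counts were not normalized by the authors as far as the table shows: they are whole numbers that sum to 16395675 to 20242356 per library. A count of read pairs without molecular identifiers is not a count of molecules, so intervals and floors cover counting error only.

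The table held 17609 gene symbols, of which 4078 had no count in any library. With the reference tables, 17313 symbols were matched to a FlyBase gene and 296 were not. The match served gene types and lists, and coordinates are those of the count table. Each column was tied to its sample by the genotype and replicate number in its name.

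Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its argument, which left 9417 genes, libraries were scaled by TMM, and dTet was compared with control by the quasi-likelihood test (glmQLFit and glmQLFTest) on all 6 libraries without covariates. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. A standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values are counts divided by the TMM-scaled library size with the cpm function of edgeR, given as mean ± SD over the 3 libraries of a group. Where a group had no count, a bound was computed against 3 counts over its 3 libraries. Where it had 1 to 3 counts, the ratio of counts is given with an exact 95% interval. Lists of genes, 40 in all, were fixed before the data were examined and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the 39 lists with at least 3 tested members; 13 passed, 5 upward and 8 downward. With a correlation estimated per list, 0 of the 39 passed camera, with 5 at an unadjusted p under 0.05. The directional test fry called 15 lists; it tests whether the genes of a list move one way on balance and does not compare the list with other genes. For 9 lists, none past the threshold, the median, the mean and the direction of camera differed in sign. Calls per chromosome arm were compared by Fisher's exact test.

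The genes named were chosen by a rule set before the data were examined: Tet and w; the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of 1 or more, with groups apart and with more than a bare number for a symbol (8 passed over in each direction); every retinal determination gene; and up to 4 genes of smallest adjusted p in each other list. Other genes are named only to spell out a small count or where the text says so. Samples, tests, alternatives and lists were also fixed before the data were examined. The lists were retinal determination, furrow and photoreceptor differentiation, antennal and head fates, Hox genes, the Notch, Hedgehog, Wnt, Dpp, EGFR, JAK-STAT and Hippo pathways, cell cycle, cell death and JNK stress, heat shock, immune response, glutathione transferases, cytochrome P450, Polycomb and Trithorax groups, methylation factors, axon guidance, neuronal genes, neuroblasts, glia, hemocytes, fat body, salivary glue, muscle, trachea and gut, sex-linked markers, ecdysone response, cuticle, eye pigment, phototransduction, glycolysis, cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded and nuclear respiratory genes, histones, and odorant and gustatory receptors.

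The alternatives were DESeq2's size factors, upper quartile scaling, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of ribosomal and small RNA genes, an adjusted p of 0.01, and each library left out in turn. The test was tried on simulated data, drawn from the control means and the fitted dispersions at the sizes of the 6 libraries. Over 9182 genes it recovered 70.7% of 99 genes changed 2-fold and 79.2% of 96 changed 4-fold, and 3.3% of its calls were false. The simulation changed few genes, equally up and down, and drew each gene independently, without differences shared across a library. Its false share therefore need not hold for the real libraries. The median log2 fold change of all tested genes was -0.02.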

Results

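RNA was measured in eye-antennal imaginal discs of Drosophila melanogaster larvae in the third instar. These discs are the epithelia that give rise to the compound eyes, antennae and head capsule of the adult. In 3 biological replicates the larvae carried ey-Gal4, a driver of the eye field, together with UAS-dTet, a transgene for the fly member of the Tet family of dioxygenases. The 3 control replicates carried ey-Gal4 over the w1118 background. The counted read pairs per library were 20242356, 19353993 and 18306991 in the controls and 16395675, 18024572 and 19966431 in the dTet discs. The design asked how dTet overexpression alters expression in the disc, because it worsened an eye phenotype whether or not a mutant histone was expressed. The histone mutant profiles of the same design were not analysed here. The first principal component held 63.5% of the variance and separated the 3 control from the 3 dTet libraries. Correlations of log2 CPM, the library-scaled count, across genes, which are not independent replicates, lay between 0.965 and 0.976 within a group and between 0.909 and 0.932 across groups.

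Tet itself, on chromosome arm 3L at 2786207 to 2879158, was measured at 349.6 ± 34.5 CPM in controls and 412.5 ± 46.3 CPM in dTet discs (mean ± SD, n = 3 each). Its log2 fold change was 0.24 (SE 0.13, 95% interval -0.04 to 0.52), and it did not pass the test (edgeR adjusted p = 0.244; 0.23 to 0.539 over the alternatives). The interval covers fold changes from 0.97 to 1.44. The control libraries stood at 315.8, 348.2 and 384.7 CPM and the dTet libraries at 364.5, 456.9 and 416.1 CPM, so the groups overlapped. Counts per gene do not part reads of the endogenous gene from those of a transgene. The white gene w, on X at 2790599 to 2796466, encodes an eye pigment transporter and is the usual marker of UAS transgenes. It fell 13.6-fold, from 55.7 ± 7.27 to 4.04 ± 1.84 CPM (log2 fold change -3.77, SE 0.29, edgeR adjusted p = 4.4e-05), with every dTet library below every control. As for Tet, the counts of w do not part the endogenous gene from copies on transgenes in either group.

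Of 9417 genes tested, 1074 (11.4%) differed between dTet and control discs, with 355 higher and 719 lower in dTet. With a 2-fold minimum, 94 were higher and 516 lower. At an unadjusted p under 0.05 the number was 2708. In 1073 of the 1074 genes the 3 libraries of one group lay wholly beyond those of the other, as they did in 32.6% of all tested genes, where chance gives 10%. The count moved by over 1.5 times when a single library was left out: it was 3231 without control replicate 1, 714 without control replicate 2, 560 without control replicate 3, 688 without dTet replicate 2 and 614 without dTet replicate 3. The higher genes numbered 131 (without dTet replicate 3) to 1408 (without control replicate 1), and the lower 424 (without control replicate 3) to 1823 (without control replicate 1). DESeq2 called 1733 genes, 658 of them higher and 1075 lower.

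The largest falls included genes of vision and of neurons. ninaB, which encodes the oxygenase that makes visual chromophore, was at 10.8 ± 1.68 CPM in controls and had no count in any dTet library, so it was at least 199.5-fold lower. Hmx was at least 83.5-fold lower, Takl1 at least 81.0-fold, Osi4 at least 77.6-fold and mah at least 70.1-fold, each against a floor of 3 counts over the 3 dTet libraries (0.0541 CPM). inaC, the protein kinase C of photoreceptors, fell from 31.9 ± 6.78 CPM to 3 counts in all, a ratio of 598.4 with a 95% counting interval of 204.4 to 2904. DIP-delta, Lim3 and Fie kept 1, 3 and 2 counts, with ratios of 546.3 (97.7 to 21620), 246.2 (83.9 to 1196) and 171.2 (47.0 to 1419). cn, an enzyme of brown eye pigment synthesis, fell from 35.6 ± 4.64 CPM to 8 counts, all of them in dTet replicate 2. The kainate-type glutamate receptor gene Ekar fell from 42.7 ± 17.1 to 0.207 ± 0.189 CPM (11 counts) and the synaptic cell surface gene dpr9 from 15.0 ± 0.936 to 0.0671 ± 0.0741 CPM (4 counts). Their edgeR adjusted p-values were 3.75e-05, 1.44e-05 and 2.03e-05. The sizes of these falls hang on single dTet libraries: the fitted fold change of cn was 235.6, but 153.1 without dTet replicate 3, and without dTet replicate 2 no dTet count was left; that of Ekar was 207.4, but 391.5 without dTet replicate 1, and that of dpr9 was 192.2, but 427.9 without dTet replicate 3. Those of inaC, DIP-delta and Lim3 without dTet replicate 1, of inaC and Lim3 without dTet replicate 3 (345.4 and 144.5) and of Fie without dTet replicate 3 also moved by over 1.5 times. The counting intervals and the floor cover counting error only.

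The largest rises were in a pair of neighbouring cytochrome P450 genes. Cyp4p2, on 2R at 9237512 to 9239831, rose 309.6-fold from 0.234 ± 0.164 to 77.8 ± 9.76 CPM (edgeR adjusted p = 4.5e-07; 520.2-fold without control replicate 1). Cyp4p1, at 9240041 to 9242139, went from 3 counts in the controls together to 716 in dTet, a ratio of 244.6 with a 95% counting interval of 83.4 to 1189 (fitted fold change 210.6, but 136.1 without control replicate 1 and 391.0 without control replicate 3). Both lie on the plus strand inside an intron of hig, a synaptic matrix gene on the minus strand at 9227785 to 9247249, and none of their exons overlaps an exon of hig. hig rose 6.58-fold (adjusted p = 1.46e-05). Cyp4p1 and Cyp4p2 are paralogs, and pairs that map to both are left out of the counts, so their levels are uncertain. Asph rose 3.58-fold and the glucuronosyltransferase gene Ugt301D1 3.34-fold. The immune-induced Listericin rose 7.74-fold, Spn47C 5.34-fold, the sodium channel gene ppk19 5.32-fold, croc 4.33-fold and yellow-e 3.26-fold. Among small RNAs, snRNA:U2:34ABa rose from 8.16 ± 5.95 to 32.9 ± 9.23 CPM and snoRNA:Psi28S-2566 3.52-fold. Pairs that map to several copies are left out of such counts. Without control replicate 1 the rise of snRNA:U2:34ABa was 6.71-fold and that of snoRNA:Psi28S-2566 5.65-fold, and without dTet replicate 2 that of Listericin was 4.99-fold. These last 7 calls ended when single libraries were left out, and that of Listericin also by limma-voom (adjusted p = 0.0541). Without control replicate 3 the adjusted p was 0.0569 for Listericin, 0.0527 for Spn47C, 0.0629 for ppk19, 0.09 for croc, 0.0834 for yellow-e, 0.0994 for snRNA:U2:34ABa and 0.0826 for snoRNA:Psi28S-2566. Calls also ended without dTet replicate 2 for Listericin (0.0893), yellow-e (0.0642) and snRNA:U2:34ABa (0.0907), without dTet replicate 3 for Spn47C (0.0637), ppk19 (0.051), croc (0.0768), yellow-e (0.0551), snRNA:U2:34ABa (0.0621) and snoRNA:Psi28S-2566 (0.0564), without dTet replicate 1 for croc (0.0672) and snoRNA:Psi28S-2566 (0.0706), and without control replicate 2 for croc (0.0819) and yellow-e (0.0591).

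The retinal determination network holds the transcription factors that specify the eye. The title of the study names this network from the same samples, so its count is not independent evidence. Of its 16 tested members, 8 fell, 3 rose and 5 did not pass, and the counts were the same when adjusted over the list alone. The eye-specifying genes so and eya fell most: so, on 2R at 7419350 to 7434872, from 100.1 ± 3.78 to 6.88 ± 1.56 CPM (14.5-fold, log2 SE 0.18, adjusted p = 1.89e-06), and eya, on 2L at 6527447 to 6546976, from 438.8 ± 42.6 to 32.2 ± 6.8 CPM (13.6-fold, log2 SE 0.17). dac fell 5.82-fold and ey, the Pax6 gene on chromosome 4 at 697689 to 721173, fell 5.38-fold from 118.1 ± 6.57 to 22.0 ± 2.66 CPM (log2 SE 0.13, adjusted p = 4.51e-06). Its paralog toy fell 1.99-fold, dan 2.41-fold, Optix 2.36-fold and danr 1.47-fold. Lim1 rose from 19.5 ± 1.05 to 39.0 ± 2.51 CPM, hth, which marks the anterior undifferentiated disc, rose 1.54-fold and eyg 1.41-fold. The log2 fold changes of nmo (0.13), exd (0.08), toe (-0.10), tio (-0.05) and tsh (-0.02) did not pass, with adjusted p from 0.634 to 0.91. The list as a whole was lower by camera (adjusted p = 0.0221), but not with an estimated correlation (adjusted p = 0.342) nor without control replicate 1 (adjusted p = 0.0735). The call of danr ended without dTet replicate 2 (adjusted p = 0.0543) or dTet replicate 3 (0.0576). That of eyg ended without control replicate 2 (0.123), control replicate 3 (0.123), dTet replicate 2 (0.121) or dTet replicate 3 (0.142).

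**Figure D1:**
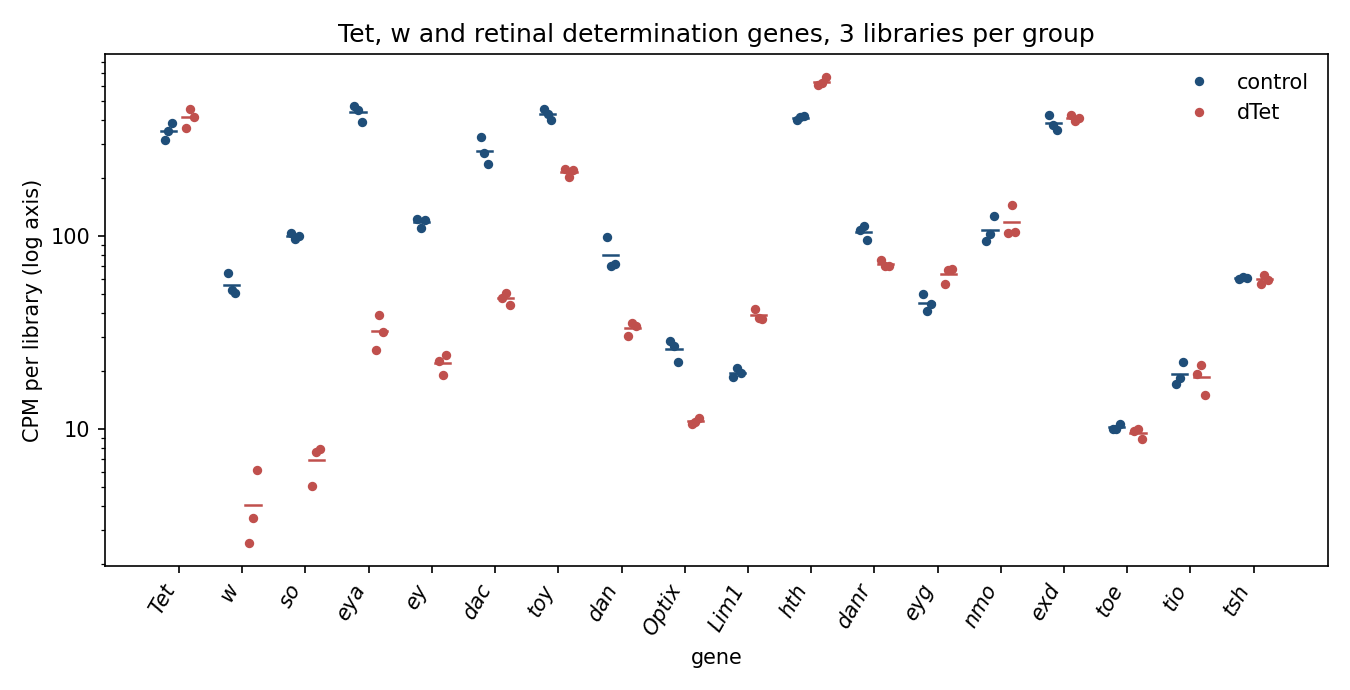
CPM of Tet, w and the 16 retinal determination genes in each of the 3 control (blue) and 3 dTet (red) libraries, on a log axis, with a line at each group mean. Tet overlaps between the groups at means of 349.6 and 412.5 CPM, whereas w, so, eya, ey and dac in every dTet library lie below every control library.

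Of 29 tested genes of the morphogenetic furrow and of photoreceptor differentiation, 20 were lower and none higher, with 9 not past the test (22 lower and 1 higher adjusted over the list alone); the median log2 fold change was -1.15 (camera adjusted p = 2.49e-11; adjusted p = 0.068 with an estimated correlation). gl, the zinc finger factor of photoreceptor fate, fell 100.8-fold from 171.7 ± 10.6 to 1.67 ± 1.02 CPM, and the receptor of R7 fate sev fell 36.8-fold from 318.3 ± 13.7 to 8.67 ± 1.8 CPM. The protease gene ru fell 36.0-fold and svp, a nuclear receptor of outer photoreceptors, 9.22-fold. Their adjusted p-values lay between 4.3e-07 and 4.51e-06. ato, the proneural gene of the founder photoreceptor, fell 1.54-fold (log2 fold change -0.62, adjusted p = 0.0218), while sens (-0.18, adjusted p = 0.491), sca (0.02, 0.92) and da (0.03, 0.91) did not pass. The call of ato ended without control replicate 2 (adjusted p = 0.0713), control replicate 3 (0.0762), dTet replicate 2 (0.0963) or dTet replicate 3 (0.108). ato, sens, sca and da were singled out after their values were seen.

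Neuronal genes were lower in 10 of 22 tested, with none higher (12 lower adjusted over the list alone; median log2 fold change -1.89; camera adjusted p = 9.34e-09; adjusted p = 0.093 with an estimated correlation). The zinc finger gene scrt fell 59.0-fold, onecut 33.8-fold, the active zone gene brp 16.5-fold and the microtubule-binding gene futsch 11.6-fold, from 383.8 ± 13.9 to 33.0 ± 2.36 CPM. The lower gene elav also stands in the photoreceptor list. Among axon guidance and cell adhesion genes, 8 of 34 were lower and 3 higher, the same numbers adjusted over the list alone, and the list did not pass camera (adjusted p = 0.133). Dscam3 fell 74.5-fold (133.6-fold without dTet replicate 1 and 48.2-fold without dTet replicate 3), robo3 23.2-fold, beat-IIIc 4.43-fold and Fas2 2.31-fold, whereas robo2, Dscam4 and sli, named after their values were seen, were higher. Calls ended for Dscam4 without control replicate 2 or 3 or any dTet library (adjusted p from 0.066 to 0.15) and for sli without control replicate 2 or any dTet library (0.0681 to 0.163). Genes of phototransduction were lower in 2 of 13 (inaC and ninaA), with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.133). Eye pigment genes were lower in 2 of 15 (cn and w), with 3 lower adjusted over the list alone (camera adjusted p = 0.133). Counts of w do not part the endogenous gene from transgene copies. ninaA had 54 counts in controls and 3 in dTet (ratio 17.6, 95% counting interval 5.7 to 87.8), all 3 in dTet replicate 2, so that no dTet count was left without that library, and its call ended without any library except dTet replicate 2, with adjusted p from 0.0574 to 0.161.

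In the EGFR pathway, which recruits photoreceptors, 6 of 16 members fell and none rose (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0183; adjusted p = 0.486 with an estimated correlation and 0.135 without control replicate 1). The 6 were the ligand-processing genes ru and rho, the ligand spi, the inhibitor aos and the transcription factors aop and pnt, and all 6 also stand in the photoreceptor list. aos fell 3.92-fold, aop 2.08-fold and pnt 1.92-fold. Of the Notch pathway and its targets, 5 of 20 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.55). The targets E(spl)mgamma-HLH and E(spl)mdelta-HLH fell 7.28-fold and 3.73-fold and E(spl)m4-BFM 2.24-fold, whereas the ligand gene Ser rose 1.71-fold, from 185.3 ± 15.2 to 317.3 ± 18.9 CPM.

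Genes of antennal and head fates moved the other way. Of 13 tested, 9 rose and 2, dan and danr, fell (10 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.84 (camera adjusted p = 0.000101; adjusted p = 0.152 with an estimated correlation). dan and danr also belong to the retinal determination list. Of 16 muscle markers 4 also rose, with a median log2 fold change of 0.56 (camera adjusted p = 0.000406; adjusted p = 0.486 with an estimated correlation and 0.0619 by fry). disco-r rose from 64.3 ± 2.57 to 134.0 ± 5.95 CPM (2.08-fold, log2 SE 0.10, adjusted p = 0.000159), and the antennal selector Dll and the homeobox gene ct rose 1.90-fold and 1.87-fold. The Hox gene Dfd, of the maxillary and mandibular head, rose 1.72-fold, and no other of the 3 Hox genes tested passed (1 higher adjusted over the list alone). The Hox list did not pass camera (adjusted p = 0.071) but did without control replicate 3 (0.0223), dTet replicate 2 (0.0296) or dTet replicate 3 (0.036). Of the Hox genes tested, Dfd and lab also stand in the antennal and head list, so the 2 lists are not separate evidence.

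Calls in the Wnt, Hedgehog, Dpp, Hippo and JAK-STAT pathways are given per list, where 11.4% of all tested genes were called. In the Wnt pathway, 3 of 17 rose and none fell, the same numbers adjusted over the list alone: wg 1.93-fold (82.2 ± 5.11 to 158.3 ± 17.3 CPM), Wnt6 2.07-fold and the secretion factor wls 1.44-fold. The list passed camera (adjusted p = 0.0136) but not with an estimated correlation (adjusted p = 0.486) or without control replicate 2 (adjusted p = 0.0586). The call of wls ended without control replicate 2 or 3 or any dTet library (adjusted p from 0.0854 to 0.117). In the Hedgehog pathway inv rose 1.96-fold and rdx fell 1.66-fold among 11 tested (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.108). In the Dpp pathway dally, 1 of 12, rose from 216.6 ± 38.5 to 325.6 ± 7.69 CPM (2 higher adjusted over the list alone; camera adjusted p = 0.125), while dpp (log2 fold change 0.45) did not pass (adjusted p = 0.0581). ft and d, which encode planar polarity and growth proteins, rose 1.40-fold and 1.29-fold among 15 Hippo pathway genes (2 higher adjusted over the list alone; camera adjusted p = 0.0684, but 0.0495 without control replicate 3). Of 9 JAK-STAT genes edgeR called 0, also adjusted over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.967); DESeq2 and limma-voom each called 1 lower, chinmo in DESeq2. The calls of dally, ft and d also ended without control replicate 2 or 3 or any dTet library, with adjusted p from 0.0638 to 0.0918, 0.0711 to 0.159 and 0.112 to 0.194.

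Among 31 cell cycle genes, the mitotic phosphatase stg fell 2.64-fold, from 154.5 ± 11.4 to 58.6 ± 2.94 CPM, and the cyclin-dependent kinase inhibitor dap fell 2.10-fold (adjusted p = 4.26e-05 and 0.000597), and no other member passed (2 lower adjusted over the list alone; camera adjusted p = 0.998). Of 18 cell death and JNK stress genes, the death gene hid rose 1.71-fold and kay, the fly Fos, 1.43-fold, whereas the TNF ligand egr fell 1.89-fold and Irbp18 1.55-fold. Members of this list thus moved both ways (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.967). Except for egr, these calls ended without single libraries: hid without control replicate 2 or 3 or dTet replicate 2 or 3 (adjusted p from 0.0794 to 0.14), kay without control replicate 2 or any dTet library (0.096 to 0.12), and Irbp18 without control replicate 2 or 3 or any dTet library (0.0596 to 0.113). Of 15 heat shock and chaperone genes edgeR called 0, also adjusted over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.699), while DESeq2 called 1 higher, Hsc70-4, and limma-voom 0. Of 14 antimicrobial and immune genes edgeR called 0, also adjusted over the list alone, and DESeq2 and limma-voom 0 (1 at an unadjusted p under 0.05). The immune list did not pass camera (adjusted p = 0.314) but did upward without control replicate 3 (0.0132) or dTet replicate 3 (0.036).

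Of the chromatin and methylation genes measured, few passed. Of 12 DNA and RNA methylation factors, Tet included, edgeR, DESeq2 and limma-voom each called 0, also adjusted over the list alone by edgeR (2 at an unadjusted p under 0.05; camera adjusted p = 0.721); vir (log2 fold change 0.24, adjusted p = 0.139) and Ythdc1 (-0.25, adjusted p = 0.141) came closest. Of 30 Polycomb and Trithorax group genes, 1 rose, the chromatin remodeler dom (1.41-fold, adjusted p = 0.023), and none adjusted over the list alone. The list passed camera upward (adjusted p = 0.043) at a median log2 fold change of 0.12, but not with an estimated correlation (adjusted p = 0.342). Its call also ended without control replicate 1 (adjusted p = 0.124), control replicate 2 (0.073), dTet replicate 1 (0.0625) or dTet replicate 3 (0.0623), with the replicate number as a block (0.0564) and with the filter at 1 CPM in 3 libraries (0.0578), and that of dom without control replicate 2 or 3 or any dTet library (adjusted p from 0.0718 to 0.103).

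Markers of other tissues that a disc preparation can hold did not move in one direction. Muscle genes were higher in 4 of 16 (bt 2.08-fold, Mhc 2.04-fold, Mp20 1.94-fold and Prm 2.32-fold; 9 higher adjusted over the list alone; camera adjusted p = 0.000406; adjusted p = 0.486 with an estimated correlation). Calls ended without control replicate 3 for Mhc (adjusted p = 0.056) and Prm (0.11), and for Prm also without control replicate 2, dTet replicate 2 or dTet replicate 3 (0.0515, 0.0958 and 0.0783). Glia markers were lower in 4 of 12, the same number adjusted over the list alone, led by loco at 1.82-fold and the glial selector repo at 2.34-fold (camera adjusted p = 0.0342; adjusted p = 0.462 with an estimated correlation, 0.149 without control replicate 1 and 0.0595 with the filter at 1 CPM in 3 libraries). The calls of repo and moody ended without control replicate 2 or 3 or dTet replicate 2 or 3 (adjusted p from 0.0506 to 0.0915 and 0.051 to 0.0927), and that of Gli without control replicate 3 or any dTet library (0.0959 to 0.13). Salivary gland glue genes, at low levels, were lower in 2 of 6 (all 6 adjusted over the list alone; camera adjusted p = 0.0122; adjusted p = 0.506 with an estimated correlation and 0.0735 without control replicate 1); Sgs8 fell from 9.1 ± 5.06 to 0.888 ± 0.609 CPM (16.6-fold without dTet replicate 3, against 10.1-fold). The other call, Eig71Ee, ended without control replicate 2 or 3 or dTet replicate 1 or 2 (adjusted p from 0.063 to 0.133). Of 13 hemocyte markers, the prophenoloxidase genes of crystal cells PPO1 and PPO2 fell 3.94-fold and 4.32-fold, and the plasmatocyte gene Hml (log2 fold change -0.32) did not pass (adjusted p = 0.171; 2 lower adjusted over the list alone; camera adjusted p = 0.55). Of 11 fat body markers edgeR, DESeq2 and limma-voom called 0, also adjusted over the list alone by edgeR (1 at an unadjusted p under 0.05; camera adjusted p = 0.541); the one of smallest p, Fbp2, stood at a log2 fold change of -1.42 (SE 0.52, adjusted p = 0.115). Neuroblast markers were lower in 2 of 12 (nab and pros, the latter also in the photoreceptor list; 2 adjusted over the list alone; camera adjusted p = 0.721). Tracheal and gut markers were higher in 2 of 8 (pio and nub; 3 adjusted over the list alone; camera adjusted p = 0.12). Of 8 sex-linked markers lncRNA:roX1 was lower, a log2 fold change of -0.53 (1 lower adjusted over the list alone; camera adjusted p = 0.998). The calls ended for nab without control replicate 2 or 3 or dTet replicate 1 or 2 (adjusted p from 0.0532 to 0.0661), for pros without control replicate 2 or dTet replicate 2 or 3 (0.0861 to 0.111), for pio without control replicate 2 or 3 or dTet replicate 2 or 3 (0.0698 to 0.119), for nub without control replicate 2 or 3 or any dTet library (0.0982 to 0.149) and for lncRNA:roX1 without control replicate 3 or dTet replicate 1 or 3 (0.117 to 0.158).

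Cytosolic ribosomal protein genes were lower as a list, with a median log2 fold change of -0.49 over 82 genes (camera adjusted p = 0.00261; adjusted p = 0.839 with an estimated correlation), although 1 gene, RpS5b, passed by itself and 0 adjusted over the list alone by edgeR. The controls differed among themselves here: ribosomal protein genes took 13.6% of counts in control replicate 1, 22.4% in control replicate 2 and 21.0% in control replicate 3, against 15.2%, 14.8% and 14.1% in the dTet libraries. Control replicate 1 thus lay below every dTet library. The 7SK small RNA took 1.06%, 2.14% and 1.74% of counts in the controls and 1.18%, 1.16% and 1.04% in dTet. Mitochondrial ribosomal protein genes had a median of -0.30 over 72 genes with 1 lower, mRpL10, and 0 adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.855 with an estimated correlation), and nuclear genes of the respiratory chain a median of -0.24 over 64 with 1 lower, ND-13A, and 0 adjusted over the list alone (camera adjusted p = 0.108). The calls of these 3 genes ended without control replicate 2 or 3 or any dTet library (adjusted p from 0.0553 to 0.155). The directional test fry called neither the cytosolic (fry adjusted p = 0.398) nor the mitochondrial (0.436) ribosomal protein list. The ribosomal protein list was no longer past the threshold without control replicate 2 (adjusted p = 0.0909) or control replicate 3 (0.0544), and the mitochondrial one without control replicate 2 (0.479), control replicate 3 (0.145), dTet replicate 2 (0.0902) or dTet replicate 3 (0.107), while the respiratory list passed without control replicate 1 (adjusted p = 1.47e-06). Glycolysis genes had a median of 0.20 over 14 with Pfk higher 1.46-fold (1 higher adjusted over the list alone; camera adjusted p = 0.0342; adjusted p = 0.342 with an estimated correlation, 0.144 without control replicate 1 and 0.0733 without dTet replicate 1). Pfk was no longer past without control replicate 2 or 3 or any dTet library (adjusted p from 0.0706 to 0.111).

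**Figure D2:**
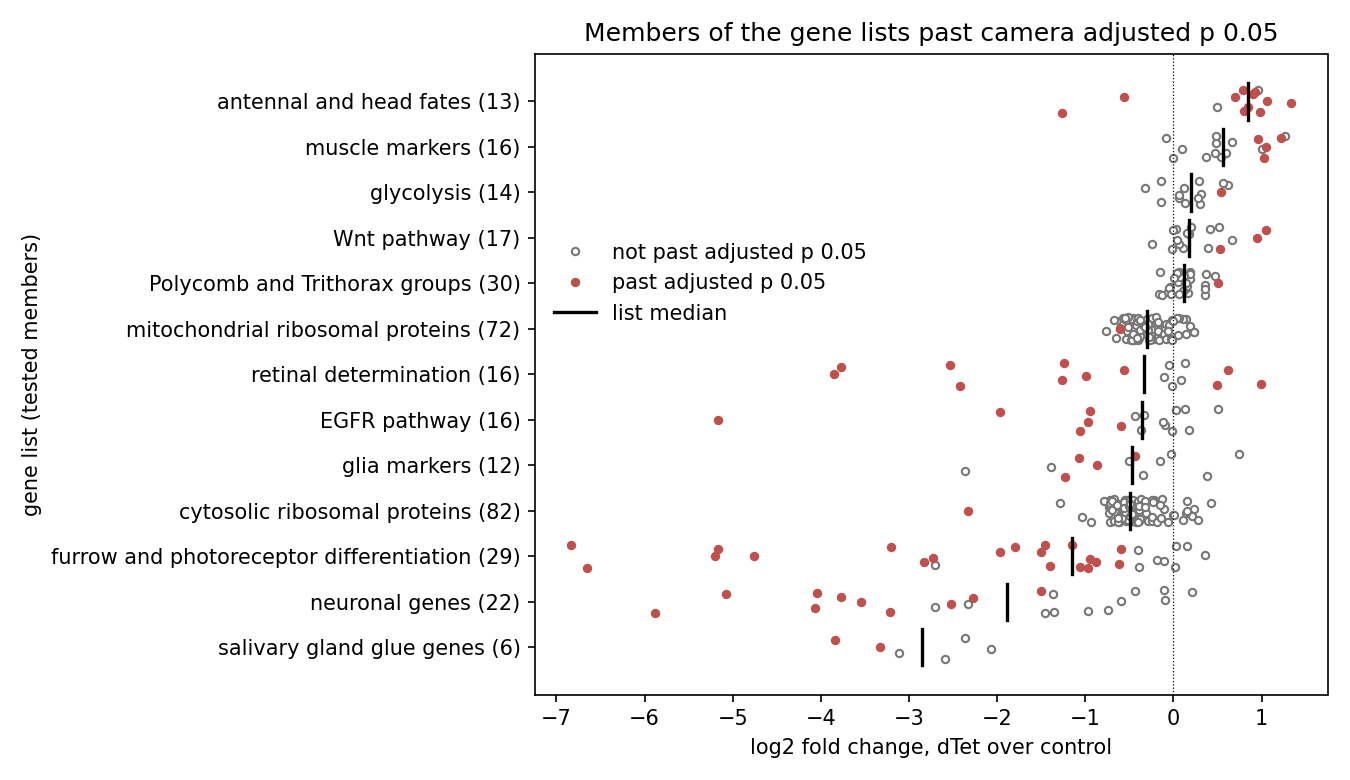
Log2 fold change, dTet over control, of every tested member of the 13 gene lists past camera adjusted p 0.05, with the number of tested members in parentheses, filled points for genes past edgeR adjusted p 0.05 and a line at each list median. Medians run from -2.85 for the salivary gland glue genes to 0.84 for antennal and head fates; with an estimated correlation 0 of the lists pass.

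In the remaining lists single genes stood out. The ecdysone response list had 4 of 22 higher and 2 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.201): ImpE1 rose 2.02-fold and the nuclear receptor Hr4 1.94-fold, while Eip93F, a factor of the onset of metamorphosis, fell 6.32-fold from 5.53 ± 0.214 to 0.871 ± 0.127 CPM. The other fall, nvd, lost its call without control replicate 2 or dTet replicate 2 or 3 (adjusted p from 0.0531 to 0.0753). Of 25 glutathione transferases, GstZ2 fell 4.90-fold, GstD3 rose from 21.0 ± 6.36 to 50.3 ± 2.14 CPM and GstD9 2.14-fold (4 higher and 2 lower in all; 4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.967). The call of GstD9 ended without dTet replicate 1 (adjusted p = 0.0555) and that of GstT3 without control replicate 3 (0.0629), dTet replicate 1 (0.0843), dTet replicate 2 (0.0505) or dTet replicate 3 (0.0761). Apart from Cyp4p2 and Cyp4p1, Cyp6d4 was the only one of 34 cytochrome P450 genes called higher by edgeR (1.49-fold), and its call ended without control replicate 2 or 3 or any dTet library (adjusted p from 0.0993 to 0.141). The P450 list had 2 higher adjusted over the list alone and did not pass camera (adjusted p = 0.558). Among 25 replication-dependent histone genes, His1:CG33801 and His2B:CG33868 were lower 10.2-fold and 2.53-fold, which is uncertain because the copies are near-identical (2 lower adjusted over the list alone; camera adjusted p = 0.452). Of 25 cuticle protein genes 2 were higher and 2 lower, with Lcp65Ad at least 54.9-fold lower, and the same numbers adjusted over the list alone (camera adjusted p = 0.998). The other called cuticle genes lost the call without single libraries: Cpr97Ea without control replicate 2 or 3 or dTet replicate 1 or 3 (adjusted p from 0.0597 to 0.13), Cpr66D without control replicate 3 or dTet replicate 1 or 3 (0.067 to 0.0909) and Cpr49Ac without control replicate 2 or 3 or dTet replicate 1 or 2 (0.0584 to 0.0756). Of 19 odorant and gustatory receptors 1 was higher, Ir76a at 1.92-fold, and 2 lower, Ir41a and Gr61a, the same numbers adjusted over the list alone (camera adjusted p = 0.998). The lower calls ended without control replicate 2 or 3 or dTet replicate 2 or 3, and for Gr61a also without dTet replicate 1 (adjusted p from 0.0573 to 0.139). The 13 mitochondrially encoded genes had no count in any library and were not tested.

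By chromosome arm, genes lower in dTet made up 5.89% of the 1563 tested genes on X against 7.98% elsewhere (odds ratio 0.721, 95% interval 0.569 to 0.906, adjusted p = 0.0489 by Fisher's exact test over 12 arm and direction tests). On the small chromosome 4, which carries ey and toy, 14 of 96 tested genes were lower (odds ratio 2.09, adjusted p = 0.108), and the other 10 tests did not pass. The X result did not pass with a 2-fold minimum (odds ratio 0.82, adjusted p = 0.509) or with the replicate number as a block (odds ratio 0.76, adjusted p = 0.208).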

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

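All alternatives below were chosen before the data were examined. DESeq2's size factors, upper quartile scaling, no filter, the filter at 1 CPM, limma-voom and removal of ribosomal and small RNA genes left the counts of called genes within 1.5 times those reported, and Tet passed the threshold in none of the alternatives (adjusted p from 0.23 to 0.539). Of the other named genes, 91 of 184 kept their direction and side of the threshold in every alternative. With DESeq2's test, which gave no adjusted p for 9 genes, 1733 genes passed, 658 of them higher, and at an adjusted p of 0.01 the test called 512 genes, 114 higher and 398 lower, and 395 with a 2-fold minimum, as a stricter threshold must lower the count. Leaving out single libraries gave 560 (without control replicate 3) to 3231 (without control replicate 1) genes, 131 to 1408 higher and 424 to 1823 lower. Of the 3231 genes, 1059 were among the 1074 reported; the cause was not tested beyond the shares of ribosomal protein genes given for that library. Of 114 called genes named besides Tet, 72 were called in each of the 6 fits without a library and 42 lost the call in at least 1. The fold changes of 17 of the 114 moved by over 1.5 times in at least 1 of these fits. With all libraries, calls ended with the replicate block for eyg (adjusted p = 0.075), ft (0.109), d (0.141), Irbp18 (0.0628), kay (0.0637), hid (0.0545), Cyp6d4 (0.0683), dom (0.075), Gli (0.0912), pio (0.0796), nub (0.0898), lncRNA:roX1 (0.0857), Cpr97Ea (0.0549), ninaA (0.0867), RpS5b (0.0751), mRpL10 (0.0601) and Ir41a (0.076). Calls also ended by limma-voom for Listericin (0.0541), RpS5b (0.0597), mRpL10 (0.0503) and ND-13A (0.0528), by DESeq2 for Eig71Ee (0.0659), without a filter for d (0.0852), nub (0.0751) and ninaA (0.0832), and with upper quartile scaling for nub (0.0504). Log2 fold changes that reversed belonged to uncalled genes and ranged over the 6 fits from -0.045 (without dTet replicate 2) to 0.264 for nmo, from -0.167 to 0.07 (0.059 without control replicate 3, 0.07 without dTet replicate 3) for tio and from -0.062 to 0.005 (without dTet replicate 1) for tsh; the cause was not tested. The gene lists past camera numbered 13, and 8 to 14 without single libraries, 7 of the 8 shared with the 13; with an estimated correlation 0 passed. The filter at 1 CPM in 3 libraries ended the calls of the glia (adjusted p = 0.0595) and Polycomb and Trithorax (0.0578) lists, the block that of the latter (0.0564), and fry did not call the salivary glue (0.0569), muscle (0.0619), cytosolic ribosomal (0.398) and mitochondrial ribosomal (0.436) lists. Outside the estimated correlation, 3 of the 13 lists passed in every alternative run on lists. These were fry, DESeq2's size factors, the filter at 1 CPM, the block and each library left out. The lists were not tested with DESeq2, limma-voom, upper quartile scaling, no filter or removal of ribosomal and small RNA genes. The odds ratio of lower genes on X was 0.8196 with a 2-fold minimum and 0.7596 with the block, neither past the threshold. Odds ratios of higher genes crossed 1 on 2L (0.9733 with the block), 3R (0.9599 with a 2-fold minimum, 0.9401 with DESeq2) and chromosome 4 (0.7294 with DESeq2); the cause was not tested. With the replicate number as a block, 902 genes passed, 279 higher and 623 lower, and 12 lists. Across genes, correlations of the deviations from the group mean between same-numbered samples were 0.031, 0.021 and -0.1, so the numbers were not taken to pair the samples, and not every sample correlated best with its own number. Genes with few counts in both groups were filtered out or untestable at this depth.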

Other observations

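The tests in this part were chosen after the results were seen, except the count over other splits of the libraries and the comparison of chromosome arms, whose interval at the 2-fold minimum was also added afterwards. The families of this and the next paragraph were picked because members of them had changed, so their counts are descriptions, and no group p-value is given. Of 18 tested Dpr and DIP genes, which encode paired immunoglobulin proteins of neurons, 10 were lower in the dTet discs and none higher, 8 lower without control replicate 3, with a median log2 fold change of -3.65 when genes without dTet counts are set to their bound. dpr12 fell from 33.1 ± 6.75 to 0.664 CPM. Of 13 Side and Beat genes, 6 were lower (5 without control replicate 3) and 1, side-V, higher; side-V lost its call without control replicate 3 or dTet replicate 2 or 3 (adjusted p from 0.0586 to 0.0696). Of 6 synaptotagmins 5 were lower (3 without control replicate 3), with Syt4 falling from 72.4 ± 13.3 to 1.18 CPM.

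All 4 tested thioester-containing protein genes, Tep1 to Tep4, which belong to the complement-like family of fly immunity, were higher in dTet, but 1 of 4 without control replicate 3 or dTet replicate 2 and 2 of 4 without control replicate 2 or dTet replicate 3. Tep2 rose from 54.5 ± 8.34 to 108.7 CPM, while edgeR called 0 genes of the immune list (1 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). The calls of Tep1, Tep3 and Tep4 ended without some single libraries: Tep1 without control replicate 2 or 3 or dTet replicate 1 or 2 (adjusted p from 0.0741 to 0.151), Tep3 without control replicate 2 or 3 or dTet replicate 2 or 3 (0.0588 to 0.0834) and Tep4 without control replicate 3 or dTet replicate 2 or 3 (0.0624 to 0.0765). Cytosolic aminoacyl-tRNA synthetases were higher in 4 of 20 (GluProRS, LeuRS, beta-PheRS and ValRS; median log2 fold change 0.37), in 14 without control replicate 1, in 2 without dTet replicate 1, in 1 without control replicate 2 or 3 or dTet replicate 2 and in 0 by edgeR without dTet replicate 3. All 4 lost the call without dTet replicate 3 (adjusted p from 0.0601 to 0.153), LeuRS, beta-PheRS and ValRS also without control replicate 2 or 3 or dTet replicate 2 (0.0501 to 0.155), and beta-PheRS and ValRS without dTet replicate 1 (0.0865 and 0.123). Of 154 snoRNA genes 7 were higher and none lower by edgeR, with a median log2 fold change of 0.62. Among all 9417 tested genes 355 were higher, and the odds ratio of snoRNA genes against the others was 1.22, so their share of calls was close to that of other genes. The higher snoRNA genes numbered 36 without control replicate 1, 2 without dTet replicate 2 and 1 without control replicate 3, dTet replicate 1 or dTet replicate 3.

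The number of called genes was set against the other ways of dividing the 6 libraries into 3 and 3. The real division gave 1074 and the highest of the others 0, so 1 of the 10 splits gave as many; 10 splits are too few for a share under 0.05. A difference of genetic background on a whole major chromosome arm was to show as an odds ratio of 1.5 or more, a bound set beforehand. Called higher and called lower genes were tested apart, and over both the largest odds ratio of a major arm was 1.15 (2R, higher, interval 0.885 to 1.49). This argues against a background excess of that size on a major arm. A smaller one stays open, since calls on all arms would dilute it. For the genes higher by at least 2-fold, a background difference stays open, as the largest odds ratio of a major arm was 1.32 (2L, interval 0.769 to 2.17). A difference on the small chromosome 4 also stays open. Its odds ratio was 2.09 for lower genes and 2.13 for genes higher by at least 2-fold. Neither passed (adjusted p = 0.108 and 0.509 by Fisher's exact test).

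Of the retinal determination genes 8 of 16 fell and 3 rose, and of the photoreceptor genes 20 of 29 fell, while 9 of 13 antennal and head genes rose and 2 fell. Younger discs are argued against as the whole cause. The undifferentiated eye field expresses ey and toy, and the smaller of their falls was a log2 fold change of -0.996 for toy (SE 0.11). A part for younger discs stays open, since tsh (-0.02) and tio (-0.05) did not pass, and the metamorphosis factor Eip93F (-2.66) and the glue genes called fell. The called genes of the ecdysone response list, which holds Eip93F, went both ways. Of its 22 tested genes 4 rose, among them ImpE1 (1.01) and Hr4 (0.96), and 2 fell. hth also rose (0.62), but within the range of the antennal and head genes (0.49 to 1.34), so its rise does not single out disc age. A smaller share of eye tissue in the libraries would raise antennal and head genes alike. The 11 such genes outside the retinal determination list had log2 fold changes from 0.49 to 1.34 with a weighted mean of 0.92 (SE 0.04). A chi-square test found no heterogeneity beyond their errors (p = 0.197), which leaves this explanation open. The SE and the test take the genes as independent, although all were measured in the same 6 libraries. dan (-1.27) and danr (-0.56), left out as retinal genes, fell. Eye genes did not move alike (gl -6.66, so -3.86, toy -0.996, tsh -0.02, sca 0.02). This does not decide, since gene totals do not show where else in the disc each is expressed. A smaller share of eye tissue with all other tissues in proportion was examined by medians over genes. The median of the 11 antennal and head genes, without dan and danr, was 0.904, against 0.076 for 48 muscle, tracheal, gut, hemocyte and fat body markers. The difference was 0.83 (permutation p = 0.00572). It was 0.74 to 1.85 for each list except muscle (adjusted permutation p of 0.00116 or less). Muscle markers were not told apart from the antennal genes (difference 0.34, adjusted permutation p = 0.091). The permutations shuffled genes measured in the same 6 libraries, so they do not cover the spread between discs. That spread was wide for fat body markers, with Lsp2 at 406.1, 114.6 and 559.1 CPM in the 3 controls. The comparison therefore does not decide. A change of eye cells towards antennal identity may have raised the list median to 0.84 as well. Gene totals of whole discs cannot tell it from a smaller share of eye tissue, so both remain hypotheses.

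Tet did not pass the threshold although the transgene was to be expressed. A wrong group label on 1 library is argued against, as the lowest correlation within a group was 0.965 and the highest between groups 0.932. Transgene transcripts may be confined to few cells of the disc, or lie partly outside the counted exons. Counts per gene hold neither cell nor position, so these remain open, with an upper 95% bound of 1.44 on the fold change of the gene total. An effect of the transgene's genotype other than its Tet transcript was not tested.

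hig and the Cyp4p2 and Cyp4p1 genes in its intron rose together, while Cyp4p3 in the same intron had 1 count in controls and 5 in dTet. A general rise of P450 genes is argued against: 1 of the other 32 tested, 3.12% (95% interval up to 16.2%), was higher. A local background difference may raise the share of called neighbours; within 100 kb it was 16% (4 of 25, none higher; interval 4.54 to 36.1%) against 11.4% elsewhere, which does not decide. An insertion of the transgene in or beside hig could also raise these genes alone, and with 0 of 25 neighbours higher (upper limit 13.7%) against 3.7% elsewhere, it and a local variant cannot be told apart because 25 neighbours are too few and the insertion site is not given in the sources used here.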
